A study of Arabidopsis thaliana with 6 samples.

How the data were processed

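RNA was measured in whole seedlings of Arabidopsis thaliana, accession Landsberg erecta, after 4 days of growth in darkness followed by 3 hours of far-red light. The 6 libraries fall into 2 groups of 3, wild type and the phyA-1 mutant, and the labels describe the 3 per genotype as independent biological replicates. Polyadenylated RNA was isolated with a column kit and made into libraries by a standard Illumina protocol, per the labels' protocols. Whether the libraries keep the strand of the RNA is not given in the sources used here.

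One table was analysed, the authors' comparison of the genotypes, which holds 1 line per gene. The aligner Bowtie and the genome build TAIR10 are named in the submitters' processing notes. The tool that estimated levels, its version and the tool behind the test are not given in the sources used here. The table has no header. Each line names the genotypes compared, phyA-1 before wild type, and the remaining columns were identified from their order and values. Their layout is that of a Cuffdiff gene table, though no label names that tool. The authors' deposited table gives 1 FPKM value for each gene and genotype, which pools the replicates. By definition FPKM is fragments mapped per kilobase of transcript, scaled to mapped fragments. Which fragments were counted, and any further scaling between libraries, are not given in the sources used here. The deposited log2 ratio, of wild type over phyA-1, matched the ratio of the 2 FPKM values within 0.001 for 99.97% of tested genes with a finite ratio. The authors also deposited a test score, a p-value and a q-value per gene. No values per library were used, so no spread between replicates could be computed here and no value carries an SD. Read depth per library is unknown, and pooled FPKM values did not yield whole-read steps from which it could be recovered. Precision at low levels is therefore known only through the deposited p-value, whose resolution ends at 5e-05, a value shared by 1668 genes.

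The table lists 33557 genes. The authors tested 22892 of them, left 10630 without a test, and gave 33 the status LOWDATA and 2 the status HIDATA, in the words of the table. A gene was called when the deposited q-value was 0.05 or below, which is the authors' own yes or no column in all tested genes. The deposited q-values are lower than a Benjamini-Hochberg adjustment over these 22892 p-values gives, and how they were computed is not given in the sources used here. Ratios are given as phyA-1 over wild type, the opposite order to the table, as log2((FPKM + 1) ratio). The pseudocount of 1 makes the change of genes with low levels look smaller than it is. Where a gene is listed at 0 in 1 genotype, no fold is given.

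Gene symbols come from the annotation of assembly TAIR10.1, where 32810 of the 33557 identifiers matched. Coordinates are those of the deposited table, written 1-based, on TAIR10 per the submitters' processing notes. Some loci in the table cover several overlapping genes. Of the 3926 called genes, 398 share a locus with another gene, and their levels are less certain, as are those of antisense partners.

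In all, 26 gene lists with 445 members were fixed before the data were examined, along with the tests of the comparison and of these lists, the rule for named genes and most of the alternatives. Tests of gene families and of patterns in the closing part were chosen afterwards. All 445 members matched the annotation and 439 were tested. Each list with at least 5 tested members was compared with all other tested genes by cameraPR of limma 3.58.1 (R 4.3.3) on the log2 ratio, 2-sided, with an inter-gene correlation preset at 0.01 and Benjamini-Hochberg adjustment over 25 lists. An estimated correlation needs values per library and was not computed. Enrichment of called genes in a list was tested by Fisher's exact test, 2-sided (SciPy 1.17.1), in each direction against all other tested genes, with adjustment over 50 tests. Counts adjusted over the list alone apply Benjamini-Hochberg to the deposited p-values of its members. Calls within 3 Mb of PHYA were compared with calls elsewhere by Fisher's exact test, and adjacent genes called in the same direction were counted against 10000 shuffles of the calls. These tests treat genes as units, and genes are not independent replicates.

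The genes named are PHYA, the 10 largest rises and 10 largest falls among called genes reaching 5 FPKM in either genotype, up to 4 called members per list by size of ratio, and the 5 called genes with the highest mean FPKM. For a list without a call, the member with the highest mean FPKM is named. One gene that the rule takes is not reported here. Other genes named were chosen after their values were seen.

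On simulated data, cameraPR over the 22892 tested genes called 96.0% of lists of 15 genes raised by 0.5 on the log2 scale, 100% of those lowered by 1, and 2.5% of those left alone. Fisher's exact test found 96.0% of simulated lists of 20 genes with 60% of members called, and 4% of lists at the background share. No rates were obtained for higher and lower genes separately, as the tests of the real lists were run. Correlation between members of the real lists is unknown, so these rates describe the simulated lists only. They do not give the share of false positives among the tests of the real lists.

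Alternatives were a q-value of 0.01, a recomputed adjustment, a minimum ratio, a minimum mean of 5 FPKM, rescaling to a median ratio of 1, pseudocounts of 0.1 and 5, the deposited test score, a correlation of 0.05, ranks, and other distances from PHYA. Leaving out genes listed at 0 or sharing a locus, and adjusting over all tested genes, were added after seeing the data.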

Results

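Transcript levels were compared between wild-type and phyA-1 seedlings of Landsberg erecta that had grown for 4 days in darkness and then received 3 hours of far-red light. Phytochrome A is the photoreceptor through which etiolated seedlings respond to continuous far-red light, and phyA-1 is a mutant of its gene. The comparison asks which genes differ between the genotypes under these conditions. No libraries from seedlings kept in darkness were included. Differences already present before the light therefore cannot be separated from a response to it. Below, rose and fell mean higher and lower in phyA-1 than in wild type. There were 3 libraries per genotype, but every level below is the authors' pooled FPKM of a genotype, with no spread between replicates, and every call is the test in the authors' deposited table. Depth per library is unknown. The median of the mean level over the 22892 tested genes was 8.86 FPKM.

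PHYA (AT1G09570, TAIR10 chromosome 1, 3095256 to 3100357) had 16.0 FPKM in phyA-1 and 167 in wild type, a log2 ratio of -3.30, with q = 0.00045 in the authors' deposited table. It was the one called member of the 5 phytochrome genes. PHYB had 29.1 and 36.4 FPKM, with q = 0.099 in the authors' deposited table. The lower position of the list by cameraPR (mean log2 ratio -0.79, median -0.31, adjusted p = 0.00052; 0.0522 with ranks) includes the mutated gene itself, and the other 4 members had a mean of -0.17 with none called. Over its alternatives the adjusted p ran from 1.27e-05 to 0.0522.

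By the q-values of the authors' deposited table, 3926 genes differed, 17.2% of those tested: 1971 were higher and 1955 lower in phyA-1. Of the called genes, 570 fell to a log2 ratio of -1 or less and 231 rose to 1 or more. The median called fall was -0.70 and the median called rise 0.56. With a q-value of 0.01 the counts were 1144 higher and 1492 lower. The share of genes called rose from 3.8% in the lowest decile of mean FPKM to 26.3% in the highest.

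**Figure D1:**
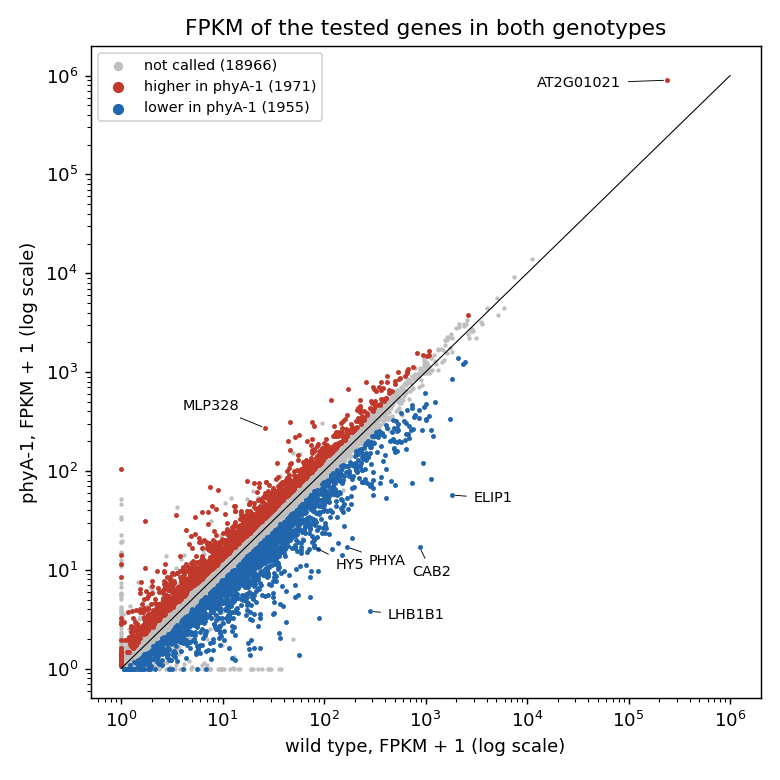
Pooled FPKM + 1 of each tested gene in wild type (x axis, log scale) and phyA-1 (y axis, log scale), 1 point per gene, coloured by the call in the authors' deposited table, with a line where both are equal. Of the called genes, 570 lower ones and 231 higher ones lie at least 1 log2 unit from the line. LHB1B1, CAB2 and ELIP1 are far below it, and AT2G01021 stands alone at the top right.

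The 10 largest falls include 4 genes of the antenna and greening lists. LHB1B1 (AT2G34430, also LHCB1.4, chromosome 2, 14524756 to 14525763), which encodes a chlorophyll a/b-binding antenna protein, had 2.79 FPKM in phyA-1 and 281 in wild type (log2 ratio -6.22). CAB2 (AT1G29920, also LHCB1.1), of the same family, had 15.9 and 873 FPKM (-5.69). Both are LHCB1 copies, near-identical in sequence, so the split of reads among them is uncertain. The early light-induced proteins ELIP1 (AT3G22840) and ELIP2 (AT4G14690), thylakoid proteins made early in greening, had 56.0 and 81.0 FPKM in phyA-1 against 1815 and 1143 in wild type. The thionin gene THI2.2 (AT5G36910) had 0.387 and 55.7 FPKM (-5.35), and AT5G48490 had 2.23 and 87.5 (-4.77). MSRB6 (AT4G04840, a methionine sulfoxide reductase, -4.17), FADA (AT4G27030, -3.96), the microRNA gene MIR163 (AT1G66725, -3.88) and AT1G48100 (-3.82) completed the 10. FADA and AT1G48100 share their loci with other genes, which makes their levels less certain. All 10 had a q-value of 0.00084 or below in the authors' deposited table.

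Among the largest rises, MLP328 (AT2G01520, chromosome 2, 235925 to 237147), of the major latex protein family, had 271 FPKM in phyA-1 and 25.4 in wild type (log2 ratio 3.37). MRN1 (AT5G42600), which encodes marneral synthase, had 34.9 and 2.50 FPKM (3.36). AT5G23840 had 68.5 and 6.58 FPKM (3.20), the B-box gene BBX23 (AT4G10240) had 62.9 and 8.05 (2.82), and AIR1 (AT4G12550) had 312 and 45.2 (2.76). SADHU3-2 (AT3G42658), a retroelement-derived locus, had 29.9 and 0.731 FPKM (4.16). The other 4 of the 10 are listed at 0 in wild type: the tRNA gene AT2G07748 at 103.5 FPKM in phyA-1, AT1G07885 at 13.02, the snoRNA gene SNOR111 at 10.5 and the transcribed pseudogene AT3G29252 at 7.35. AT2G07748 and SNOR111 have the same p in the authors' deposited table, 0.00135, as 29 other called genes listed at 0 in wild type, so these 2 calls are less certain.

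Genes of light signalling split in both directions. Of 31 tested members, 13 fell, 5 rose and 13 were not called, with 13 lower and 6 higher when adjusted over the list alone. Those that fell include BBX32 (0.235 FPKM in phyA-1, 12.3 in wild type), BBX31 (0.802 and 16.7), RUP2 (2.62 and 31.3) and HYH (8.72 and 73.9). HY5, the bZIP factor that promotes photomorphogenesis, had 16.0 and 77.9 FPKM (log2 ratio -2.21), and SPA1, a partner of the COP1 ubiquitin ligase, also fell (-2.80). FHY1 and FHL, which carry phytochrome A into the nucleus, rose (1.06 and 0.94). BBX25 (AT2G31380, locus shared) had 0.971 and 48.3 FPKM but was not called (q = 0.131 in the authors' deposited table). The list shifted lower by cameraPR (mean -0.90, median -0.15, adjusted p = 3.53e-19; 0.0031 with ranks). The mean lies far below the median, so the largest falls weigh heavily in it. The list was enriched among lower genes by Fisher's exact test (adjusted p = 3.26e-06).

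Nuclear genes of the photosynthetic apparatus fell nearly throughout. All 21 antenna genes fell, with log2 ratios from -6.22 to -0.95 and a median of -1.64 (cameraPR, adjusted p = 3.87e-82). LHCB2.2 had 75.0 FPKM in phyA-1 and 738 in wild type, and LHCA1 had 119 and 933. The LHCB1 copies are near-identical in sequence and ranged from -6.22 to -0.95, so the split of reads among them is uncertain. CAB1 (AT1G29930, also LHCB1.3), 1 of the 5 called genes with the highest level, had 1250 and 2421 FPKM. All 28 nuclear genes of the photosystem cores and electron transport fell too, within a narrower range of -1.99 to -0.79 (adjusted p = 4.57e-37). PSBO2 had 70.1 and 282 FPKM, PSAN 105 and 407, PSAH2 167 and 637, and PSAD-2 80.3 and 299.

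Of 18 Calvin cycle genes, 16 fell and 2 were not called (mean -1.06, cameraPR adjusted p = 2e-17). CP12-2, a regulator of the cycle, had 15.3 FPKM in phyA-1 and 85.8 in wild type, FBA1 73.3 and 286, and GAPA-2 75.4 and 236. Among the Rubisco small subunit genes, which are similar in sequence, RBCS1B (log2 ratio -1.67), RBCS3B (-0.96) and RBCS2B (-0.60) fell by different amounts, and how reads were divided among them was not measured here. RBCS3B and RBCS2B were among the highest called genes, at 1194 and 1390 FPKM in phyA-1.

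In chlorophyll biosynthesis, 15 of 21 genes fell, 2 rose and 4 were not called (adjusted p = 1.83e-11). GUN4 had 26.8 FPKM in phyA-1 and 158 in wild type, GUN5, the H subunit of magnesium chelatase, 56.2 and 302, HEMA1 19.3 and 78.4, and CRD1, whose locus is shared, 153 and 505. The 2 that rose were the protochlorophyllide oxidoreductases PORA (1.13) and PORB (1.11), while PORC fell (-1.13). Of 15 carotenoid and plastid isoprenoid genes, 10 fell and 5 were not called, 12 falling when adjusted over the list alone (mean -0.69, adjusted p = 4.75e-07). PSY, phytoene synthase, had 26.9 and 102 FPKM. CYP97A3 (-1.16, locus shared), ABA1 (-0.93) and CLA1 (-0.87) followed.

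All 13 regulators of greening and early light-induced proteins fell (mean -1.82, adjusted p = 1.73e-36). Besides the ELIP genes, the sigma factor gene SIGE (SIG5) had 2.59 FPKM in phyA-1 and 30.7 in wild type, and the GATA factor CGA1 had 0.435 and 5.03. Across these 6 plastid lists, 103 of 116 tested genes fell, 2 rose and 11 were not called.

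Flavonoid and anthocyanin genes fell as a list (mean -1.05, adjusted p = 2.26e-23), with 12 of 27 called lower, 1 higher and 14 not called, and 14 lower when adjusted over the list alone. F3H (locus shared) had 7.42 FPKM in phyA-1 and 72.5 in wild type, UGT78D2 4.89 and 30.5, CHIL 9.15 and 51.8, and PAP1, a MYB activator of anthocyanin genes, 1.03 and 8.20. CHS, chalcone synthase, whose locus is shared, had 55.0 and 184 FPKM. MYBL2, a repressor of the pathway, rose (0.58). DFR (0.018 and 1.396 FPKM) and LDOX (0.101 and 3.20 FPKM), which act late in anthocyanin synthesis, were not called.

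Of 24 clock genes, 13 fell, 1 rose and 10 were not called, or 14 and 2 when adjusted over the list alone (mean -0.46, adjusted p = 4e-05). EPR1 (log2 ratio -2.02), ELF4 (-1.78) and LHY (-1.31) fell, and BOA rose from 9.16 FPKM in wild type to 22.7 in phyA-1. All 5 nitrogen assimilation genes fell, GLU1 (-1.37) and the nitrate reductase genes NIA1 (-1.19) and NIA2 (-1.01) most, and NIR1 by less (-0.55; list adjusted p = 5e-05). Of 12 genes of photorespiration and the peroxisome, 7 fell and 3 rose. HPR (-2.06), GGT1 (-1.60) and GOX2 (-1.38) were among those that fell, and the 3 that rose, ICL (1.21), MLS (0.90) and PCK1 (0.99), act in the glyoxylate cycle and gluconeogenesis of lipid mobilisation. That list's adjusted p was 0.00052, but 0.18 with ranks, within a range of 1.17e-05 to 0.18 over its alternatives.

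Stomatal lineage genes fell in 4 of 7 cases, EPF2 (-1.71), SPCH (-0.81), STOMAGEN (-0.52) and TMM (-0.40), with an adjusted p of 0.0067 by cameraPR. Their enrichment among lower genes (Fisher's exact test, adjusted p = 0.0047) was lost with a q-value of 0.01 (adjusted p = 0.149, within 0.0046 to 0.149 over the alternatives).

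Auxin genes were shifted higher. Of 40 members, 19 rose, 2 fell and 19 were not called, or 20 and 3 when adjusted over the list alone (mean 0.39, cameraPR adjusted p = 0.00012; Fisher's exact test among higher genes, adjusted p = 1e-09). IAA29, an auxin-induced Aux/IAA gene, had 17.2 FPKM in phyA-1 and 3.70 in wild type, IAA6 42.0 and 19.3, and SAUR63 15.6 and 6.58. The SAUR gene AT4G38840 (SAUR14) fell (18.0 and 42.6 FPKM). SAUR genes lie in clusters of similar copies, and as sharing of reads among them was not measured, single values are uncertain. Dark-inducible genes rose in 6 of 8 cases (mean 0.64, adjusted p = 0.00087), with SEN1 (DIN1) at 201 and 43.7 FPKM, ASN1 (DIN6) at 50.3 and 21.6, and DIN11 at 2.69 and 1.12. DIN9 fell (-0.96).

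Seed maturation genes rose in 8 of 15 tested cases, none fell, and 9 rose when adjusted over the list alone (mean 0.72, adjusted p = 4.75e-07). The storage protein genes CRA1 (10.5 FPKM in phyA-1, 1.71 in wild type), CRU3 (18.0 and 5.15) and SESA2 (5.05 and 0.769) rose, as did ABI5 (10.6 and 3.95), a factor of the abscisic acid response in seeds. SESA3 (5.11 and 5.57 FPKM) and the oleosin gene OLEO1 (2.24 and 2.26 FPKM, locus shared) were not called. No member exceeded 18.0 FPKM.

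In the shade-marker list, 5 of 12 genes rose and 3 fell. HB-2 (46.5 FPKM in phyA-1, 19.4 in wild type) and HAT3 (17.6 and 7.99), homeodomain genes induced by shade, rose. PIF4 (-1.01) and UNE10 (PIF8, -1.77) fell. This list was enriched among higher genes (adjusted p = 0.0062) without a shift of its mean (0.06, adjusted p = 0.86), and when adjusted over the list alone 5 rose and 5 fell. Cell wall genes also split, with 9 of 25 higher and 5 lower. The xyloglucan endotransglucosylase genes XTH15 (515 and 117 FPKM), XTH5 (23.9 and 7.24) and XTH17 (118 and 44.8) rose, and EXPA10 fell (24.8 and 52.3). Their enrichment among higher genes had an adjusted p of 0.00049, and their shift one of 0.0554, which passed with a pseudocount of 5 (0.0081; range 0.0081 to 0.453).

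Apart from the abscisic acid and cold list, the other hormone lists went both ways. In the gibberellin list 6 of 17 rose, 3 fell and 8 were not called, or 7 and 3 when adjusted over the list alone. GA2OX8 (1.14) and the DELLA gene GAI (1.02) rose, and GA3OX2 (-1.56) and GASA6 (-1.52) fell. Its mean (-0.13) and median (0.16) differ in sign, its shift had an adjusted p of 0.326, and its enrichment among higher genes (adjusted p = 0.0062) was lost at a q-value of 0.01 (0.119, range 0.006 to 0.119). The lowest ratio of the list, -3.62 for GA2OX1, which was not called, pulls its mean down. GASA4, among the 5 highest called genes, had 3769 and 2593 FPKM. Ethylene genes rose in 4 of 14 cases, ACS8 (1.60), ACS5 (1.18) and HLS1 (0.91) among them, and fell in 3, with EIN3 at 24.4 and 84.9 FPKM (shift adjusted p = 0.86). Brassinosteroid genes rose in 3 of 14 cases, BEE3 (0.83), CYP72C1 (0.58) and BAS1 (0.55), and BR6OX1 fell (-0.41), with 4 rising when adjusted over the list alone (adjusted p = 0.385). Of 15 tested jasmonate genes, TIFY7 (JAZ9, -1.65) and AOC2 (-0.55) fell and MYC2 rose (0.50), with mean and median of opposite sign (-0.06 and 0.03, adjusted p = 0.624). In the abscisic acid and cold list only DREB1A (0.541 and 1.75 FPKM) of 12 was called, and the list's shift (adjusted p = 0.0011) was lost at a mean of at least 5 FPKM (0.572) and with the deposited test score (0.239; range 0.00013 to 0.572).

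Cell cycle genes stood near 0, with 1 of 20 called, CYCD3;1 (-0.54; mean -0.0032, adjusted p = 0.86). Of 4 root markers, too few for a list test, EXPA18 rose (28.3 and 20.9 FPKM). None of 16 reference genes was called by the authors' deposited table, and none had an unadjusted p of 0.05 or below there. Their log2 ratios ran from -0.30 to 0.34, GAPC1 having 970 and 1089 FPKM (list adjusted p = 0.568). For lists where no separate count is given, adjustment over the list alone gave the same counts.

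**Figure D2:**
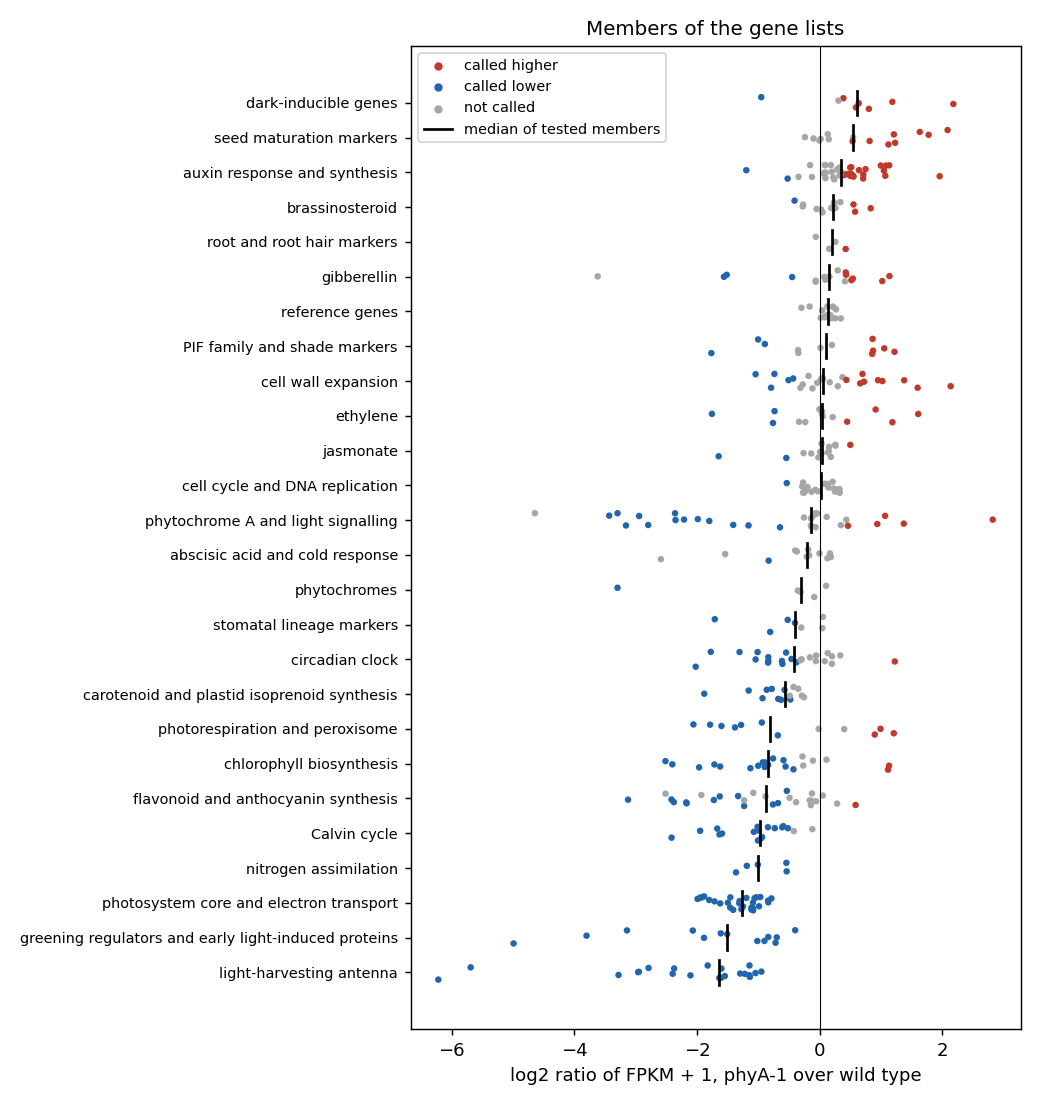
Log2 ratio of FPKM + 1, phyA-1 over wild type (x axis), for each tested member of the 26 gene lists (y axis, ordered by median), 1 point per gene, coloured by the call in the authors' deposited table, with a bar at the median. Antenna genes have the lowest median (-1.64) with all 21 members called lower, and dark-inducible genes the highest (0.61).

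Over the 25 lists tested, 14 shifted lower, the phytochrome list with PHYA among them, 3 higher and 8 did not pass. Genes with at least 5 FPKM in both genotypes had a median log2 ratio of 0.08. The highest level of all was AT2G01021 (chromosome 2, 6571 to 6672), with 898139 FPKM in phyA-1 and 239694 in wild type, which is 50.5% and 21.8% of the summed FPKM of the genotypes. FPKM is scaled by length and this locus is short, so these percentages are not shares of reads. Whether the reads counted there come from an mRNA of AT2G01021 was not tested. No excess of called genes was detected around PHYA: within 3 Mb 259 of 1609 tested genes were called (16.1%), against 3666 of 21282 elsewhere (17.2%; Fisher's exact test, odds ratio 0.92, p = 0.258). With a q-value of 0.01 they were fewer near PHYA than elsewhere (Fisher's exact test, odds ratio 0.83, p = 0.0286, odds ratios of 0.83 to 0.95 over the alternatives). Adjacent genes were called in the same direction in 546 of 22887 pairs, against a mean of 336 and a highest of 406 in 10000 shuffles (permutation p = 0.0001, the smallest the shuffles can give). The shuffles move calls among genes of any level and do not set apart adjacent copies of similar sequence. They therefore cannot say what the excess stems from.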

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

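The flags below rest on genes outside the authors' test, and the tests of the patterns in this part were all chosen after the results were seen.

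Of the genes that the authors' deposited table leaves untested, 7 have at least 5 FPKM in phyA-1 and more there than in wild type. MT1A (AT1G07600), a metallothionein gene, has 40511 FPKM in phyA-1 and 35412 in wild type. CIB1 (AT4G34530), a bHLH gene of cryptochrome signalling, has 15.3 and 8.45 FPKM, and PIA1 (AT5G07840), a phytochrome-interacting ankyrin protein gene, 22.5 and 18.4. AT3G17998 has 50.4 and 49.3 FPKM, AT2G43018 23.3 and 21.2, AT1G07730 16.8 and 15.3, and AT2G35747 12.1 in phyA-1 while listed at 0 in wild type. All 7 share their loci with other genes. Their status in that table is LOWDATA and no test was made, so these differences have no error.

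Genes listed at 0 in 1 genotype make up 89 of the calls, 46 at 0 in wild type and 43 at 0 in phyA-1, with a median of 0.226 FPKM in the other genotype. Below 1 FPKM, 24.1% of the 315 such genes were called, against 2.2% of 3159 genes above 0 in both. These groups are not matched for size of ratio, which is most extreme at 0, so their shares alone say nothing about the test. Of the called genes, 31 share a p of 0.00135 in the authors' deposited table, at levels from 0.087 to 103.5 FPKM, and a candidate explanation is that the authors' test gives such genes p-values that hardly depend on their own reads. Over all 404 tested genes listed at 0 in 1 genotype, Spearman's rho across genes, which are not independent replicates, was -0.04 between p and FPKM (permutation p = 0.418) and -0.12 between p and FPKM times locus length (permutation p = 0.0157), too weak to decide for or against it. That explanation and a true on or off difference between the genotypes cannot be told apart without values per library.

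The opposite also occurs. Among protein-coding genes with at least 5 FPKM in 1 genotype and an absolute log2 ratio of at least 2, 25.9% of the 27 genes below 0.5 FPKM in the other genotype were called, against 96.0% of the 126 others (Fisher's exact test, p = 6.55e-15). GA2OX1 (AT1G78440), with 0.020 FPKM in phyA-1 and 11.6 in wild type, has a p of 0.154 in the authors' deposited table, as do DFR and COR15B. DFR is below 5 FPKM in both genotypes and so is not among the 27. The test may therefore treat genes near 0 in 1 genotype apart from others with as large a ratio. Libraries of a genotype that differ from each other in these genes would also give large p-values, which pooled values leave open.

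Called genes with an absolute log2 ratio of at least 1 fell more often than they rose, 231 of 801 being higher. A shift of scale between the genotypes, as when a few genes such as AT2G01021 take most of the FPKM, could tilt such a count. A uniform shift toward falls would put the median gene below 0. Genes with at least 5 FPKM in both genotypes had a median log2 ratio of 0.077 (95% bootstrap interval over genes 0.071 to 0.082). For the values as deposited, this argues against a uniform shift toward falls only if the median gene is taken as unchanged. The interval covers the sampling of genes, not the spread between libraries. How the levels were scaled between libraries, beyond the definition of FPKM, is not given in the sources used here. That scaling may itself have set a median near 0. The difference in genotype stays open and was not tested against other explanations.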

How the results depend on the processing

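Leaving out genes listed at 0 or with a shared locus, and adjusting over all tested genes, were chosen after seeing the data. No paired analysis was possible because the deposited values pool the replicates of each genotype, and for that reason the replicate block, leaving out each replicate and other splits of the samples were not run. Depth limits are unknown for the same reason. Requiring an absolute log2 ratio of 1 left 231 higher and 570 lower genes, and a q-value of 0.01 left 1144 higher ones. Rescaling to a median ratio of 1 cannot change calls made by q-value alone. With rescaled values, an absolute log2 ratio of at least 1 left 198 higher and 639 lower genes. Of the 14 alternative counts without rescaling, 11 stayed within 1.5 times, and adjustment over all tested genes gave 1715 and 1835. For named genes, neither another pseudocount nor so small a rescaling could turn a direction, so they test nothing. Of 173 alternative list shifts, 162 kept direction and side. Ranks gave adjusted p-values of 0.0522 for phytochromes and 0.18 for photorespiration, no longer passing, and turned gibberellin (0.35) and ethylene (0.88). Ethylene also turned with a pseudocount of 5 (0.545) and at a mean of 5 FPKM (0.283), and the shade list with a pseudocount of 0.1 (0.918), none passing in either direction. The abscisic acid list ceased to pass at 5 FPKM (0.572) and with the test score (0.239). Cell wall genes passed with a pseudocount of 5 (0.0081) and without genes at 0 (0.0363). Of 146 alternative enrichments, 140 kept both. At a q-value of 0.01, higher gibberellin (0.119) and lower stomatal (0.149) genes lost theirs, and odds turned for higher jasmonate (0.866) and lower abscisic acid genes (0.866). At 5 FPKM odds turned for higher chlorophyll and jasmonate genes (both 1). The odds ratio around PHYA at a q-value of 0.01 was 0.83, which passed. The cause was not tested in any of these.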

Other observations

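The gene families in this part were grouped by annotated product name and tested after the data were seen, and no hypothesis is attached to them. Of 316 families with at least 10 tested members, 632 Fisher's exact tests were run over both directions, with Benjamini-Hochberg adjustment. SAUR-like genes were over-represented among higher genes, with 24 of 74 higher and 7 lower (adjusted p = 3.83e-06), 17 of the 74 being in the gene lists above as well. AT4G09530 had 29.0 FPKM in phyA-1 and 10.1 in wild type. Root hair specific genes rose in 8 of 14 cases and fell in 0 (adjusted p = 0.0007), RHS13 having 90.9 and 49.7 FPKM. Defensin-like genes rose in 6 of 10 (adjusted p = 0.0044), AT3G63360 having 119 and 46.7 FPKM. Peroxidases rose in 15 of 62 and fell in 6 (adjusted p = 0.0104), and berberine-bridge family genes rose in 7 of 16 and fell in 1 (adjusted p = 0.0104). Xyloglucan endotransglucosylases rose in 11 of 26 cases and fell in 1 (adjusted p = 0.00068), 9 of the 26 being in those lists. Sharing of reads among similar copies in these families was not measured, so single values are uncertain.

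Plastid-lipid associated (fibrillin) genes fell in 8 of 11 cases (adjusted p = 7.67e-05), AT5G19940, whose locus is shared with another gene, having 40.5 FPKM in phyA-1 and 98.3 in wild type. Plastid transcriptionally active chromosome genes fell in 6 of 13 (adjusted p = 0.019), with PTAC16 at 29.2 and 83.1 FPKM. Heat shock protein genes fell in 8 of 25 and rose in 0 (adjusted p = 0.0362), with HSP70 (AT3G12580) at 18.1 and 54.7 FPKM. Thioredoxin family genes fell in 14 of 53 and rose in 4 (adjusted p = 0.0066). Genes with a cytochrome name fell in 37 of 212 cases and rose in 24 (adjusted p = 0.0028 for lower), 8 of the 212 being in the gene lists. Expansins went both ways, 7 of 20 lower and 4 higher (adjusted p = 0.0395 for lower), 10 of the 20 being in the gene lists. Genes of ribosomal proteins were under-represented among higher genes, with 2 of 235 higher and 8 lower (adjusted p = 7.67e-05). Among lower genes their odds ratio was also below 1 (0.37, Fisher's exact test, adjusted p = 0.0874). Of all 22892 tested genes, 1971 were higher and 1955 lower. Pentatricopeptide repeat genes were under-represented among higher genes too, with 2 of 187 higher and 13 lower (adjusted p = 0.0018). So were tetratricopeptide repeat genes, with 6 of 258 higher and 26 lower (adjusted p = 0.0038), 1 of the 258 being in the gene lists.

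Restricting adjacent pairs to loci that do not overlap gave 535 pairs called in the same direction against a mean of 311 in shuffles (permutation p = 0.0001, the smallest the shuffles can give). That restriction does not remove adjacent copies of similar sequence. All 279 genes of the plastid and mitochondrial genomes in the table are listed at 0 in both genotypes, and none was tested. Such values cannot be read as absence of their transcripts, so genes encoded in the plastid are not covered by the results above.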
